A study of Rattus norvegicus with 98 samples.

How the data were processed

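Messenger RNA was measured in nasal epithelial cells of 98 male F344/NCrl rats, 8 weeks old, on Affymetrix Rat230_2 arrays, 1 array per animal. Per the labels, proteases released the cells from the lateral meatus and the nasoturbinate of a section of the nose (level II), after removal of olfactory epithelium and the maxilloturbinate. RNA was extracted with a Qiagen micro RNA kit and labelled by the standard Affymetrix protocol. Rats inhaled formaldehyde with the whole body for 6 h per day on 5 days per week at 0, 0.7, 2, 6 or 15 ppm, or received 40 ul of 400 mM formaldehyde or of water in each nostril.

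The deposited values are on the log2 scale, 1 value per probe set and array. The scale was read from the values, which ran from 2.67 to 14.83, and the sorted values of the 98 arrays differed by an SD of at most 0.065, so the authors had normalized between arrays. How the authors summarised probes, corrected background and normalized is not given in the sources used here. The deposited file held 31099 probe sets; 57 Affymetrix control probe sets were left out and 31042 were tested. No array was left out, and no pair of arrays was identical. Correlations of 2 arrays across probe sets lay between 0.9287 and 0.9953. RNA integrity numbers, given for 85 arrays, ran from 7.2 to 8.8 with a median of 8.2. Arrays give no counts, so the number of animals limits the precision.

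Groups followed the labels: dose, route, time of collection and array set, 24 groups of 4 or 5 animals. Array set 1 held 82 arrays with air, 0.7, 2 and 6 ppm at 5 times, and array set 2, the later one, held 16 arrays with air, 15 ppm, water and instilled formaldehyde at 6 h. The time of 8 days is on the labels and not in the design text of the series. The treatment field of the 0.7 ppm animals at 8 days reads 0.07 ppm, while the rest of their labels read 0.7 ppm, which was used. No paired analysis was possible because each animal gave 1 array. The time of day of collection is not given in the sources used here.

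Gene symbols came from the array's probe annotation, updated by gene identifier to the RefSeq genes of the GRCr8 rat assembly, from which no coordinates were used. Of the probe sets tested, 20826 had 1 symbol, 436 had several and 9780 had no listed gene. A gene was represented by its probe set with the highest mean over the 98 arrays, giving 14217 genes, 4525 of them with more than 1 probe set. Counts are of probe sets.

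Computation used R 4.3.3, limma 3.58.1 and, to read the values, version 1.17.8 of the data.table package. A linear model with 1 coefficient per group and no covariate was fitted in limma to the 98 arrays, with 74 residual degrees of freedom, followed by moderated statistics with a constant prior. The 17 comparisons of a dose with its control used air animals of the same time and array set, or water for instillation. The model also gave F-tests of the air animals across 5 times and of the 6 ppm effect across 5 times, a comparison of the air animals of both array sets at 6 h, and tests of the difference between the 15 ppm effect and the instillation or the 6 ppm effect, 22 comparisons in all. Tests were two-sided. P values were adjusted by Benjamini-Hochberg over the 31042 probe sets within a comparison, and a probe set was called at an adjusted p under 0.05, with no fold threshold. Standard errors are those of the model, and SDs are between the animals of a group. Separation was counted where every exposed animal lay beyond every control animal.

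Gene lists were tested by camera in limma with a preset correlation of 0.01 between genes against the other genes, adjusted over the 25 lists within a comparison. A correlation estimated from the residuals and fry were the alternatives. The 16 pathway lists were oxidative stress (Nrf2 targets), heat shock, unfolded protein and integrated stress response, p53 targets, DNA crosslink repair, aldehyde metabolism, cell cycle, inflammatory mediators, immediate early response, wound repair and EGFR ligands, interferon response, xenobiotic monooxygenases, glycolysis and hypoxia, cholesterol synthesis, circadian clock and mitochondrial respiration. The 9 cell type lists were basal and squamous epithelium, ciliated cells, secretory cells, olfactory epithelium, neutrophils, macrophages and dendritic cells, lymphocytes, erythroid cells, and stroma and vessels. Of 479 list entries 415 had a probe set. Lists of skeletal muscle, glucocorticoid-responsive and ribosome biogenesis genes were added after the values were seen and were adjusted among themselves.

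The groups, the comparisons, the tests, the threshold, the 25 lists, the rule for named genes and most alternatives were set before the data were examined. The rule names, per comparison, the 12 largest rises and the 12 largest falls among called genes whose groups separated, up to 4 members of each list with the smallest p and any member behind a list count of 5 or fewer, and always Adh5, Aldh2, Nqo1, Hmox1, Cdkn1a, Mki67, Hspa1a, Krt5, Foxj1, Muc5ac and S100a9. For tests of differences and for air animals it names the 10 genes with the smallest p. A gene named for 1 comparison may be given for another, and probe sets of a gene that differ are stated. Genes outside the rule were chosen after their values were seen, and these include Nop56, Gnl3 and Tsc22d3.

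Alternatives set in advance were cyclic loess between arrays, arrays centred on their median, probe sets with a mean above the median only, only the compared groups in the fit, an intensity trend with a robust prior, air animals of both array sets as the control of 15 ppm, and each animal left out in turn. Chosen after the data were seen were the mean of the olfactory list as a covariate, the first array set's air animals as the control of 15 ppm, and the omission of 2 air animals at 5 days with muscle transcripts. Alternatives on a pseudocount were not run because the values were already logarithms. Other splits of the animals were refitted, 35 for 4 against 4 and otherwise 100 drawn with a fixed seed. For differences between effects, the residuals of an additive model were shuffled among the animals in place of the labels. Single values were compared by exact permutation, and pooled values by permutation within time points.

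The fit was tested on simulated data with 10 runs per comparison and, per run, 50 genes changed at each fold, up or down at random. The noise was the shuffled residuals of the fit, which were not rescaled and spread less than the animals do. The shares found are therefore likely too high. At 6 ppm and 6 h the fit found 31.0%, 77% and 94.4% of genes changed 1.25-fold, 1.5-fold and 2-fold, and 6.4%, 48.2% and 87.2% with only the compared groups in the fit. Per run, 24.1 other probe sets were called on average, and with no change simulated at most 6 were. For the 6 ppm effect across times it found 9.6%, 56% and 87.8%. With no change in the simulated data, camera with the preset correlation called up to 12 of 25 lists in a run, 8.7 on average, and with an estimated correlation 0, so list calls are given with both.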

Results

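Gene expression was measured in the lining of the nose of 98 male F344 rats, each rat on 1 array of 31099 probe sets, so every replicate was a separate animal. Formaldehyde is a reactive gas that binds protein and DNA where it first meets tissue, and the nose of the rat, which breathes through it alone, takes up most of an inhaled dose. Rats inhaled air or 0.7, 2 or 6 ppm and were collected at 6 h, 24 h, 5 days, 8 days or 19 days. A later set of 16 arrays held rats collected at 6 h after inhaling air or 15 ppm, and rats given 40 ul of water or of 400 mM formaldehyde into each nostril. There were 24 groups, 22 of 4 animals and 2 of 5 animals (2 ppm at 5 days and air at 8 days). Deposited log2 values ran from 2.67 to 14.83, array medians lay between 5.93 and 6.07, and 2 arrays of 1 group correlated at 0.9621 or more across probe sets. The number of animals limits the precision of every value below. With spiked changes, 77% of genes changed 1.5-fold and 94.4% of genes changed 2-fold at 6 ppm and 6 h were found, shares that are likely too high because the simulated noise was not rescaled. Named genes are given by the probe set with the highest mean signal. The genes named most often were Hmox1 (1370080_at), Srxn1 (1372510_at), Maff (1380229_at), Tnfrsf12a (1371785_at) and Areg (1369871_at).

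The first question was what a single 6 h exposure to 15 ppm did, a concentration that injures the nasal lining of rats. Areg, an EGF receptor ligand released by injured epithelium, rose 28.9-fold (log2 change 4.85 ± 0.52, SE, n = 4 per group; adjusted p = 2.09e-11), and Plaur and Tnfrsf12a, receptors of wound repair, each rose 11.7-fold. Hmox1, which breaks down heme under oxidative stress, rose from 7.81 ± 0.26 to 11.18 ± 0.31 (log2, SD, n = 4), or 10.3-fold. Srxn1 and Slc7a11, which maintain thiol defences against electrophiles, rose 6.53-fold and 5.83-fold. The transcription factors Egr2, Fosl1 and Maff rose 11.2-fold, 10.6-fold and 7.9-fold, the neutrophil attractants Cxcl1 and Cxcl2 9.91-fold and 6.15-fold, the monocyte attractant Ccl2 6.34-fold and the prostaglandin synthase Ptgs2 6.79-fold. Among genes that fell, Uts2r, the urotensin receptor, was 4.39-fold lower, and Chodl, Bmyc and Gnai1 were 3.39-fold, 2.6-fold and 2.54-fold lower. Pou2af3, a cofactor of the tuft cell program, was 2.18-fold lower and Ntf3, a nerve growth factor, was 2.14-fold lower. Against the air animals of the first array set the log2 changes of Areg, Egr2, Plaur and Hmox1 were 3.60, 1.02, 2.91 and 3.56, where they were 4.85, 3.48, 3.55 and 3.37 against their own. The second probe sets of Plaur, Egr2 and 1 of 3 for Srxn1 did not follow (log2 change 0.14, 0.17 and −0.09).

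In total 2636 probe sets changed at 15 ppm, 1340 up and 1296 down, of which 146 rose and 22 fell at least 2-fold. The share that rose was 50.8%, and it was 62.7% after cyclic loess between arrays (1595 up, 950 down). All 4 exposed animals lay beyond all 4 air animals in 16.34% of probe sets, against 2.86% by chance. Against the air animals of the first array set 4763 probe sets changed, with 937 rises and 678 falls shared, and 22 of the 24 genes with the largest changes were called the same way; Cxcl2 and Adamts15 were not. All 24 were called whichever animal was left out.

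By gene list at 15 ppm, heat shock chaperones moved together: 11 of 15 rose (13 adjusted over the list alone), among them Dnaja1 (log2 change 0.80 ± 0.09, SE) and Hspb1 (1.82 ± 0.28), with a list adjusted p of 6.25e-16 by camera and 9.57e-06 with an estimated correlation. Genes that p53 turns on after DNA damage followed, with Gadd45a up 3.11-fold and the cell cycle inhibitor Cdkn1a up 2.23-fold among 5 of 16 that rose (8 up and 1 down adjusted over the list alone; adjusted p = 0.000519 with an estimated correlation). Immediate early genes rose in 13 of 25 cases (18 adjusted over the list alone; 0.0112), and the unfolded protein and integrated stress response had 6 rises and 1 fall among 19 (7 up and 1 down adjusted over the list alone; 0.0172), with Ddit3 up 4.43-fold and Atf3 5.99-fold. Wound repair genes and EGF receptor ligands rose in 6 of 19 cases (6 adjusted over the list alone; 0.0358), Hbegf among them at 5.12-fold. Nrf2 targets, the genes of oxidative defence, had 6 rises and 1 fall among 20 (7 up and 2 down adjusted over the list alone), and inflammatory mediators 6 rises among 25 (15 adjusted over the list alone); both list calls were lost with an estimated correlation (adjusted p = 0.0974 for each). Hspa1a, the inducible chaperone, stood 0.83 above its own air animals and −0.44 from those of the first set. Against the first set's air animals the heat shock and p53 lists held with an estimated correlation (adjusted p = 0.00948 and 0.00145), and the immediate early, stress response and wound lists did not (adjusted p = 0.769, 0.177 and 0.522).

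Of the cell types at 15 ppm, neutrophil genes rose in 4 of 10 cases (4 adjusted over the list alone), with S100a8 up 4.47-fold and S100a9 up 3.86-fold; this list call was lost with an estimated correlation (adjusted p = 0.458), and against the first set's air animals 2 genes rose and 1 fell. Xenobiotic monooxygenases fell in 3 of 14 cases (5 adjusted over the list alone; median −0.22), clock genes had 2 rises and 4 falls among 16 (2 and 7 adjusted over the list alone; median −0.29), and 2 of 17 genes of glycolysis and hypoxia rose (2 adjusted over the list alone), with adjusted p = 0.14, 0.172 and 0.206 with an estimated correlation. Against the first set's air animals the clock list turned to a median of 0.03, with 1 rise and 1 fall. Aldehyde metabolism was not called: Adh5 and Aldh2, which clear formaldehyde, differed from air by −0.15 ± 0.14 and −0.21 ± 0.15 (log2, SE) without being called, while Akr1b8, Cbr1 and Akr1b1 rose, 3 of 20 members (3 adjusted over the list alone). DNA crosslink repair had 1 rise (Sprtn) and 1 fall (Fancl) among 17, the cell cycle 1 rise (Pcna) and 1 fall (Racgap1) among 31, cholesterol synthesis 2 rises and 2 falls among 13, mitochondrial respiration 1 rise (Ndufb5) among 15, the interferon response 1 fall (Ifi27) among 16, and basal and squamous epithelium 1 rise (Sfn) among 24. Adjusted over the list alone these 6 lists gave the same counts except mitochondrial respiration, with 0. Of the 83 genes of ciliated, secretory, olfactory, macrophage and dendritic, lymphoid, erythroid, and stromal and vascular cells, 0 were called in limma over all probe sets, 0 adjusted over the list alone, and 1 had an unadjusted p under 0.05. The camera adjusted p of these 14 lists lay between 0.142 and 0.984. Against the first set's air animals cholesterol synthesis had 4 falls and no rise, stromal and vascular genes had 3 falls and mitochondrial respiration 2 (adjusted p = 0.821, 0.678 and 0.821 with an estimated correlation).

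**Figure D1:**
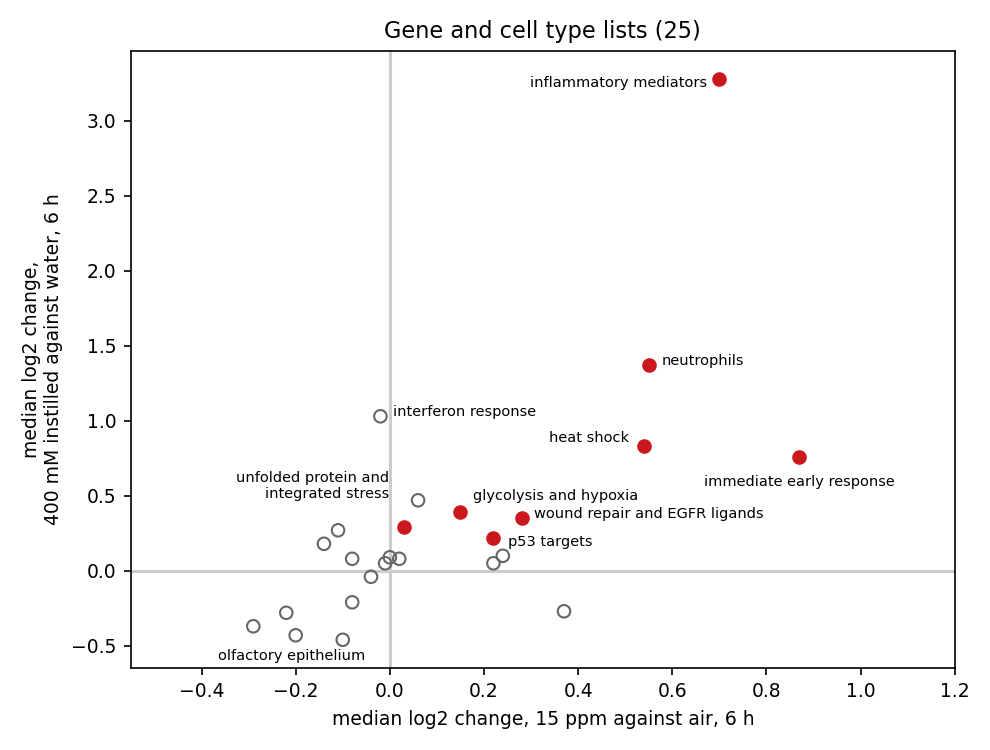
Median log2 change of the genes of each of the 25 lists, for 15 ppm against air (horizontal axis) and 400 mM instilled against water (vertical axis), with 4 animals per group. Filled points passed the set test with an estimated correlation in at least 1 of the comparisons; inflammatory mediators lie at 0.70 and 3.28.

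Instillation placed formaldehyde on the lining as a liquid, and its effect at 6 h was measured against water. Mediators that call in white blood cells dominated: Ccl2, the monocyte attractant, rose 54.7-fold, from 5.40 ± 0.40 to 11.17 ± 0.84 (log2, SD, n = 4; adjusted p = 5.95e-22), Ccl3 23.0-fold, Cxcl1 21.9-fold and Cxcl2 21.3-fold. The fever cytokines Il1a and Il1b rose 22.5-fold and 20.7-fold, Csf3, which releases neutrophils from the marrow, rose 18.4-fold, and Ptgs2 20.5-fold. Areg rose 22.6-fold and Plaur 19.5-fold, with the other probe set of Plaur at a log2 change of 0.45. Uts2r was 5.56-fold lower, the potassium channel gene Kcnj1 4.43-fold, Tsku 3.56-fold and Nat8f5 3.49-fold, and Gmnc, which starts the ciliated cell program, was 2.96-fold lower. Tox3 and Gpr155 fell by 1.67 and 1.54 in log2, and another probe set of each differed from water by 0.03 and 0.12. All 24 genes with the largest changes after instillation were called whichever animal was left out.

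After instillation 23 of 25 inflammatory mediators rose (25 adjusted over the list alone; median log2 change 3.28), with adjusted p = 0.000305 with an estimated correlation. Neutrophil genes rose in 8 of 10 cases (8 adjusted over the list alone; 0.0439), with the chemokine receptor Cxcr2 up 5.6-fold and Csf3r 11.5-fold. Heat shock genes had 10 rises and 1 fall among 15 (the same adjusted over the list alone; 0.000305), Hspb1 up 8.12-fold, and p53 targets 7 rises and 2 falls among 16 (7 and 3 adjusted over the list alone; 0.00554). The unfolded protein and integrated stress response had 9 rises and 2 falls among 19 (10 and 2 adjusted over the list alone; 0.0111), glycolysis and hypoxia 8 rises among 17 (12 adjusted over the list alone; 0.0234), and wound repair 10 rises among 19 (11 up and 1 down adjusted over the list alone; 0.0382). Interferon genes rose in 11 of 16 cases (12 adjusted over the list alone), with Ifit3 up 11.3-fold and Isg15 6.68-fold, and 16 of 25 immediate early genes rose and 1 fell (19 and 1 adjusted over the list alone). Those list calls were lost with an estimated correlation (adjusted p = 0.118 and 0.0628), as were 5 further ones: clock genes, 1 rise and 7 falls among 16 (adjusted p = 0.0962), xenobiotic monooxygenases, 6 falls among 14 (0.13), lymphoid genes, 2 rises among 14 (0.59), Nrf2 targets, 4 rises and 2 falls among 20 (0.711), and ciliated cell genes, 2 falls among 11 (0.711). In all 6892 probe sets changed, 3052 up and 3840 down, of which 469 rose and 302 fell at least 2-fold, and 18.7% separated all 4 exposed animals from all 4 water animals (2.86% by chance).

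Inhalation and instillation were compared to ask what depends on the route and the dose it delivers. Most of the 15 ppm response was shared: 927 of its 1340 rises and 995 of its 1296 falls were also called after instillation, against 131.7 and 160.3 for independent sets, and 1 rise was called the opposite way. Among 149 genes whose effects differed, inflammatory mediators stood out. The effect on the chemokine Ccl7 at 15 ppm differed from that of instillation by −3.18 ± 0.34 (log2, SE, n = 4 per group; adjusted p = 5.69e-10), that on Il6 by −3.11, on Csf3 by −3.50, on the scavenger receptor gene Olr1 by −3.22 and on Ccl4 by −2.89. Il6 rose 13.5-fold after instillation and was not called at 15 ppm (log2 change 0.64 ± 0.28, SE; adjusted p = 0.155). The effects on 13 of 25 inflammatory mediators differed, all 13 lower at 15 ppm (list median −2.26), and this was the only list to hold with an estimated correlation (adjusted p = 0.000183; interferon response 0.0604). In all 273 probe sets differed between the effects, 101 positive and 172 negative. Of 100 refits with shuffled residuals 6 gave as many, the real one included, so chance could not be excluded for this number. The count moved with single animals: 484, 574 and 104 without instilled animals 369, 372 and 374, and 172 and 167 without water animals 355 and 352.

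At 6 ppm the inhaled concentration was followed over 19 days, starting with 6 h. Of its 35 rises, 15 were also called at 15 ppm. Hmox1 rose 3.04-fold, from 7.62 ± 0.10 to 9.23 ± 0.43 (log2, SD, n = 4; adjusted p = 2.26e-05), Maff 2.91-fold, Tnfrsf12a 2.73-fold and Srxn1 2.1-fold. Txnrd1, a thioredoxin reductase, and Sqstm1, an adaptor of autophagy, rose 1.52-fold and 1.31-fold, and Coq10b, which serves the respiratory chain, 1.48-fold. Of the squamous genes, Sprr1b and Tgm3, which build the tough envelope of stratified epithelium, rose by 2.51 ± 0.56 and 1.77 ± 0.42 (log2, SE), a rise carried by animals 286 and 287: without animal 286 the Tgm3 value was 0.58 and without 1 animal that of Sprr1b was as low as 1.41. Their calls were lost in 6 and 5 of 8 fits that left out 1 animal, and the median of the 24 squamous genes was −0.24. Evi2a was 2.77-fold lower, and Ooep and the death ligand Tnfsf10 were each 2.47-fold lower. The antigen presentation gene RT1-Da was 1.66-fold lower, Pou2af3 1.65-fold lower and the clock gene Bmal1 1.67-fold lower, while Per2, its counterpart, rose by 0.61 ± 0.13. Other probe sets of Srxn1, Txnrd1, Sqstm1, Per2 and Dtx4 differed from air by as little as 0.07, 0.21, 0.12, 0.13 and −0.02. Of the 24 genes with the largest changes, Hmox1, Maff, Tnfrsf12a, Ooep and Dtx4 were called whichever animal was left out, and the other 19 lost their call without at least 1 animal.

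At 6 ppm and 6 h 76 probe sets changed, 35 up and 41 down; after cyclic loess 75 changed, 69.3% of them up against 46.1%. All 4 exposed animals lay beyond all 4 air animals in 8.82% of probe sets (2.86% by chance). Without exposed animal 283, 284 or 286 the count was 197, 35 or 38, and without air animal 49, 50, 52 or 53 it was 15, 19, 21 or 33. Of the 76 probe sets, 8 also differed between air animals of 24 h and of 8 and 19 days (10.5%, against 4.6% of all probe sets), Per2, Bmal1 and Sqstm1 among them. In the Nrf2 list 3 of 20 genes rose (6 adjusted over the list alone), in the clock list 1 rose and 1 fell (5 and 1 adjusted over the list alone), and 1 of 12 macrophage and dendritic cell genes fell (3 adjusted over the list alone; median −0.47). The 7 list calls, which included olfactory genes at a median of 0.47 and cholesterol synthesis at −0.30, were all lost with an estimated correlation (smallest adjusted p = 0.419).

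**Figure D2:**
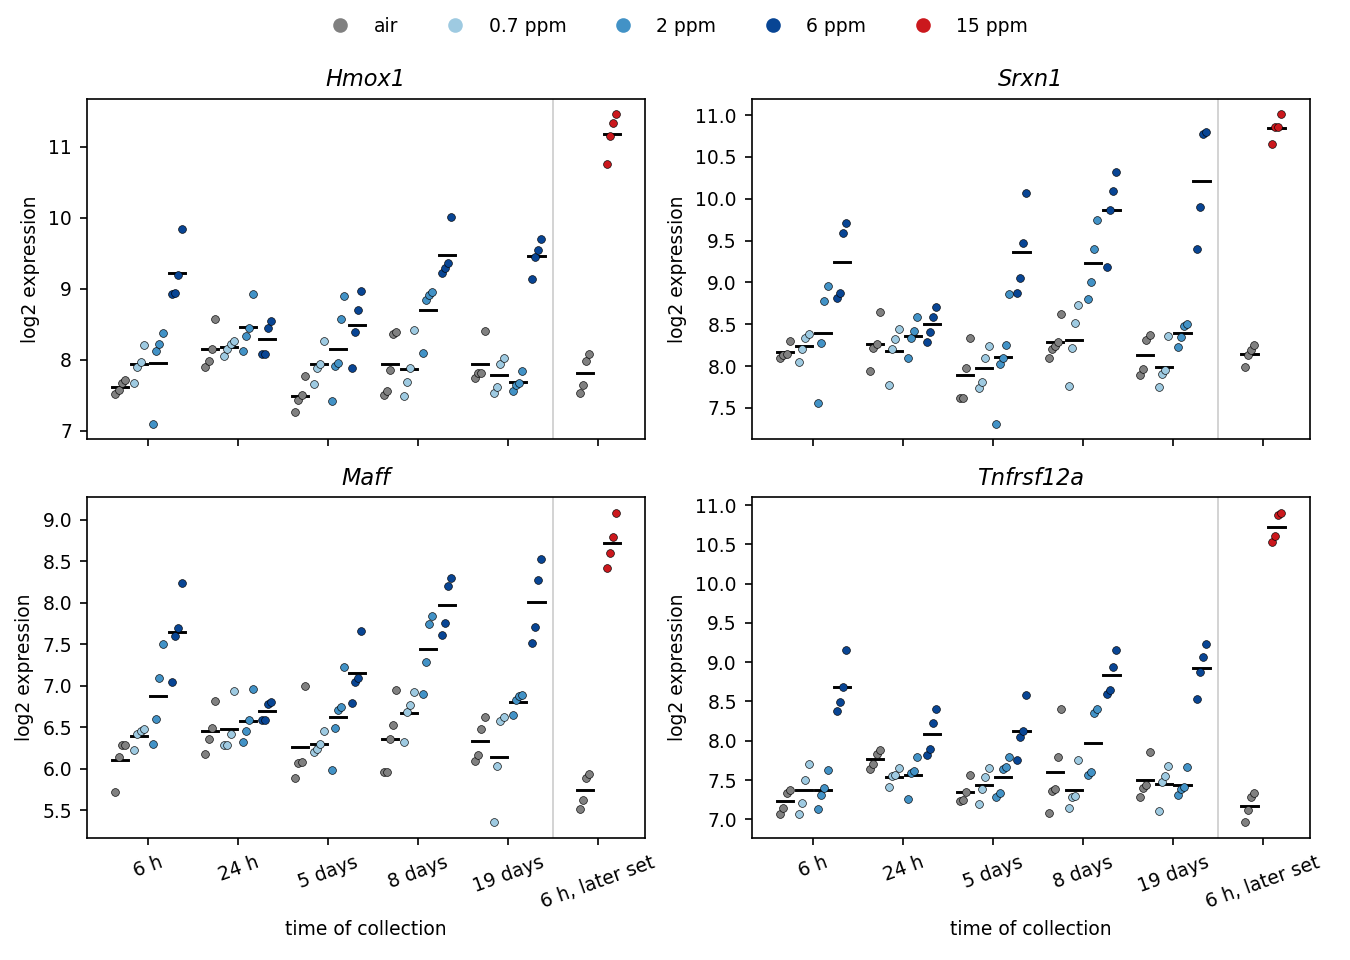
Log2 level of Hmox1, Srxn1, Maff and Tnfrsf12a in each animal, by time of collection and inhaled dose; points are animals, bars are group means and the 15 ppm animals at 6 h stand beside the air animals of their own array set. At 6 ppm the Hmox1 mean was 9.23 at 6 h and 9.46 at 19 days.

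At 6 ppm and 24 h none of those genes was called: Hmox1 differed by 0.14 ± 0.23 (log2, SE, n = 4 per group), Srxn1 by 0.23 ± 0.245, Maff by 0.23 ± 0.25 and Tnfrsf12a by 0.32 ± 0.19. As exposure lasted 6 h per day, these animals may have spent hours without formaldehyde before collection. That interval cannot be told apart from the time of collection. A single probe set rose, which has no listed gene, and 2350 probe sets had an unadjusted p under 0.05 in limma. The groups separated in 4.41% of probe sets (2.86% by chance). Without exposed animal 289 or 292 the count was 6 or 0, and without air animal 56, 57 or 58 it was 0, 20 or 0. Cell cycle genes lay above air (median 0.15 over 31 genes, 1 rise adjusted over the list alone), which was 1 of 8 list calls lost with an estimated correlation (adjusted p = 0.562).

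After 5 days at 6 ppm Slc7a11, the cystine importer, rose 2.99-fold (log2 change 1.58 ± 0.34, SE, n = 4 per group; adjusted p = 0.0225), Srxn1 2.79-fold and Hmox1 1.99-fold, with Slc3a2, the partner of Slc7a11, up 1.22-fold. Mthfd2, of mitochondrial one-carbon metabolism, rose 1.47-fold and Ppargc1a, which drives mitochondrial genes, 1.61-fold. Per2 rose 1.88-fold and Wee1, a kinase gene under clock control, 1.74-fold, while Bmal1 was 1.56-fold lower and Ooep 2.2-fold lower. The other probe set of Per2 differed from air by 0.23, and the lowest of the Srxn1 probe sets by 0.10. Srxn1, Slc25a15, Per2, Wee1 and Mthfd2, 5 of the 16 genes with the largest changes, were called whichever animal was left out. In all 37 probe sets changed, 28 up and 9 down, and 4.2% separated the groups (2.86% by chance). Skeletal muscle transcripts were high in air animals 60 and 61, and without both of these animals 12 probe sets were called, 10 of them among the 37, and 2 of 16 genes with the largest changes held. Without exposed animal 293, 294, 296 or 297 the count was 20, 60, 23 or 24, and without air animal 60 or 61 alone it was 19 or 21. Nrf2 targets had 3 rises among 20 (8 adjusted over the list alone; median 0.21), cholesterol synthesis genes fell in 7 of 13 cases adjusted over the list alone and in 0 over all probe sets in limma (10 at an unadjusted p under 0.05), and 5 of 14 lymphoid genes fell adjusted over the list alone (0 over all probe sets, 7 at an unadjusted p under 0.05). Of the 37 probe sets, 10 also differed between air animals of 24 h and of 8 and 19 days (27.0%, against 4.6% of all probe sets), among them Per2, Bmal1, Mthfd2, Slc3a2 and Slc25a15. None of the 12 list calls held with an estimated correlation (adjusted p = 0.117, 0.056 and 0.202 for these lists).

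At 8 days 9 probe sets changed at 6 ppm, all upward, and 7 of them had also risen at 6 h. RNA integrity numbers, where given, were lower in the exposed animals (7.77 ± 0.058, SD, n = 3) than in air (8.36 ± 0.261, SD, n = 5), as at 6 h (7.73 ± 0.058, n = 3, and 8.15 ± 0.238, n = 4). Maff rose 3.06-fold, Srxn1 2.97-fold, Hmox1 2.9-fold, from 7.94 ± 0.43 (SD, n = 5) to 9.47 ± 0.36 (SD, n = 4), and Tnfrsf12a 2.34-fold, each with adjusted p = 2.01e-05. Sqstm1 rose 1.33-fold and Gpr83, a receptor gene near the floor of detection, 1.82-fold. Other probe sets of Srxn1 and Sqstm1 differed from air by as little as −0.06 and 0.02. Maff, Srxn1, Hmox1 and Tnfrsf12a were called whichever animal was left out; Sqstm1 and Gpr83 were not. The groups separated in 1.65% of probe sets, against 1.59% by chance. Without exposed animal 298 or 299 the count was 4 or 15, and without air animal 64 or 66 it was 5 or 4. Squamous genes lay below air (median −0.53), as did olfactory genes (−0.69) and 11 of 31 cell cycle genes adjusted over the list alone (median −0.30); none of the 15 list calls held with an estimated correlation (adjusted p = 0.379, 0.401 and 0.229 for these lists, 0.0627 for Nrf2 targets with a median of 0.26).

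At 19 days of 6 ppm Areg rose 4.9-fold (log2 change 2.29 ± 0.52, SE, n = 4 per group; adjusted p = 0.0198), Fosl1 2.51-fold, Srxn1 4.24-fold, Maff 3.17-fold, Hmox1 2.85-fold, Tnfrsf12a 2.69-fold and Slc7a11 2.58-fold. Osgin1, an oxidative stress gene that restrains growth, rose 1.86-fold and Pvr, an adhesion receptor that immune cells recognise, 1.81-fold. Ascl3 and Foxi1, transcription factors of ionocytes and of secretory duct cells, were 1.95-fold and 1.65-fold lower, and Ooep was 2.33-fold lower. Sirt3, a mitochondrial deacetylase, and Acsm3, of mitochondrial acyl metabolism, were each 1.65-fold lower, and Clec4a and Stap1, of white blood cells, 1.82-fold and 1.8-fold lower. The lowest of the Srxn1 probe sets differed from air by −0.14. Whichever animal was left out, 8 of the 24 genes with the largest changes were called, namely Srxn1, Maff, Hmox1, Tnfrsf12a, Fosl1, Coq10b, Ooep and Ascl3. In all 128 probe sets changed, 28 up and 100 down. The share of rises, 21.9%, became 36.2% with array medians aligned (25 up, 44 down) and 61.6% after cyclic loess (61 up, 38 down). Nearly all calls were lost with only the compared groups in the fit, as they were at 8 days. Other alternatives raised the count, and all are given below. The groups separated in 6.77% of probe sets (2.86% by chance). Without exposed animal 312 the count was 28, and without air animal 73, 75 or 76 it was 30, 34 or 84. Squamous genes lay above air (median 0.53) and macrophage and dendritic cell genes below (−0.46, 5 of 12 falls adjusted over the list alone). With Nrf2 targets (4 of 20 rises, and 7 up and 1 down adjusted over the list alone) these were among 7 list calls, none of which held with an estimated correlation (adjusted p = 0.634, 0.601 and 0.36). Of the 12 macrophage and dendritic cell genes, 6 had an unadjusted p under 0.05 in limma at 6 ppm. Against the same air animals there were 9 at 2 ppm and 1 at 0.7 ppm.

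**Figure D3:**
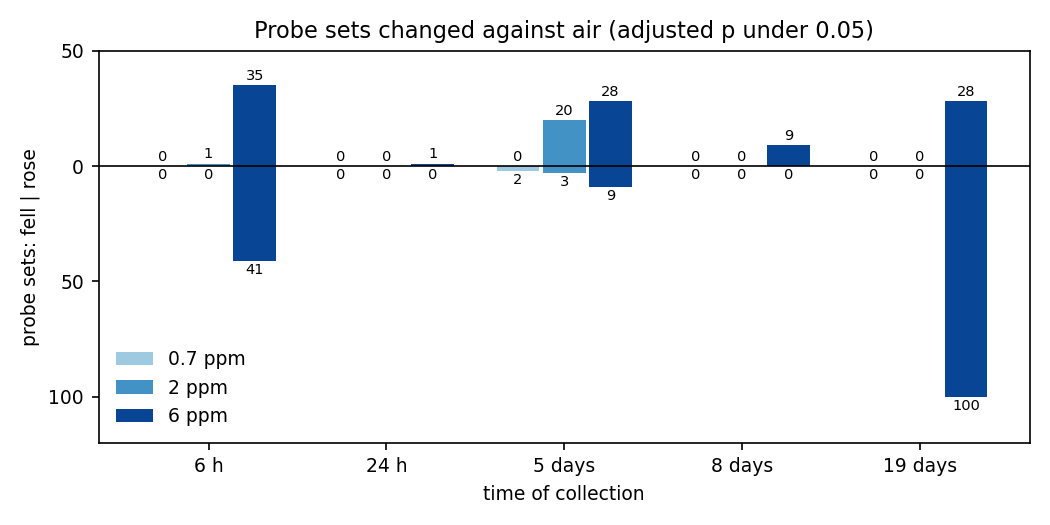
Number of probe sets that rose (above 0) and fell (below 0) against air at each time for 0.7, 2 and 6 ppm, in groups of 4 or 5 animals. The longest bar is that of the 100 falls at 6 ppm and 19 days, where 28 probe sets rose.

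Across the 5 times, Hmox1 and Srxn1 were called at 6 ppm at 4 times each, all but 24 h, and Maff, Tnfrsf12a, Coq10b, Ooep, Bmal1 and Stx8 at 3 times each. Whether the effect itself changed with time was tested directly, and 4 probe sets passed, with 1 gene, Per2. Its effect was 0.61 ± 0.13 at 6 h, −0.19 ± 0.13 at 24 h and 0.91 ± 0.13 at 5 days (log2, SE; adjusted p = 0.0201). Srxn1 (adjusted p = 0.0743) and Hmox1 (0.171) did not pass, although the Hmox1 effect at 24 h differed from that at 6 h by −1.47 ± 0.33 (log2, SE). The number of probe sets with an unadjusted p under 0.05 was 1895. Without 6 ppm animal 284 (6 h), 297 (5 days) or 308 (19 days) the count was 8, 7 or 8.

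To ask what separates 15 ppm from 6 ppm at 6 h, each effect was taken against the air animals of its own array set. Egr2 responded more at 15 ppm by 3.62 ± 0.43 (log2, SE, n = 4 per group; adjusted p = 1.45e-08), Fosl1 by 2.75 ± 0.35, Tnfrsf12a by 2.10 ± 0.27, Gadd45a by 1.70 ± 0.19, Ppp1r15a, which ends the block on translation after stress, by 1.55 ± 0.20, and the tumour suppressor Rassf1 by 1.37 ± 0.145. Heat shock genes were higher in 7 of 15 cases (adjusted p = 6.09e-06 with an estimated correlation), p53 targets in 3 of 16 (0.000682), immediate early genes in 10 of 25 (0.0106), and wound repair genes in 4 of 19 (0.0174). The unfolded protein and integrated stress response differed by 5 positive and 1 negative of 19 (0.0174), clock genes by 5 negative of 16 (0.0214), and xenobiotic monooxygenases by 1 negative of 14 (0.0381). In all 370 probe sets differed, 317 positive and 53 negative. The count was 238 without 6 ppm animal 284, 214 without 15 ppm animal 342 and 238 without air animal 325 of the later set. The air animals of the array sets themselves differed at some of these genes, Egr2 by −2.46 and Ppp1r15a by −0.72, so the size of those differences depends on which air animals serve as controls. For Fosl1 (−0.42) and Tnfrsf12a (−0.06) the air sets were not called different. The list differences depend on that choice as well: against the first set's air animals the 15 ppm calls of the immediate early, wound repair and unfolded protein lists did not hold with an estimated correlation (adjusted p = 0.769, 0.522 and 0.177), and the clock list median was 0.03. That comparison mixes dose with array set. Immediate early means were also low in the later set's water animals (8.43 to 8.75, first set's air 8.91 to 9.36). A shift common to the later set, which its own air animals would cancel, is therefore possible.

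At 2 ppm calls came mainly after 5 days. Per2 rose 1.8-fold (log2 change 0.85 ± 0.13, SE, n = 5 and 4; adjusted p = 0.0001), Coq10b 1.78-fold, Slc25a15, a mitochondrial ornithine carrier, 1.71-fold and Wee1 1.57-fold, and Bmal1 was 1.52-fold lower. Cd163, a scavenger receptor of macrophages, rose 1.62-fold. Hmox1 and Srxn1 were not called at 2 ppm at any time, with the highest differences from air at 8 days (0.77 ± 0.22 and 0.94 ± 0.23, log2, SE). At that time Srxn1 was higher in every exposed animal (8.8 to 9.75) than in every air animal (8.1 to 8.62). Of 20 Nrf2 targets 8 had an unadjusted p under 0.05 in limma at 8 days, and 0 were called. A weaker response at 2 ppm therefore stays open. At 5 days the other probe set of Per2 differed from air by 0.25, and the probe sets of Slc25a15 by between 0.03 and 0.94. Per2 and Coq10b were called whichever animal was left out; the other 4 genes were not. Clock genes had 1 rise and 1 fall among 16 at 5 days (8 and 2 adjusted over the list alone; adjusted p = 0.114 with an estimated correlation). Olfactory and ciliated cell genes lay below air (medians −0.82 and −0.37), and stromal and macrophage genes above (0.34 and 0.32), list calls that were lost with an estimated correlation (adjusted p = 0.654, 0.497, 0.497 and 0.497). In all 23 probe sets changed at 5 days, 20 up and 3 down, and 2.16% separated the groups (1.59% by chance), while 0 were called in limma without air animals 60 and 61 together. Without exposed animal 215, 216, 217 or 219 the count was 13, 122, 6 or 10, and without air animal 60 or 62 it was 2 or 15. Of the 23 probe sets, 9 also differed between air animals of 24 h and of 8 and 19 days (39.1%, against 4.6% of all probe sets), Per2, Bmal1, Slc25a15 and Cd163 among them. The limma counts at 6 h, 24 h, 8 days and 19 days were 1, 0, 0 and 0, with 1742, 1751, 1317 and 2682 probe sets at an unadjusted p under 0.05, and the 1 probe set at 6 h has no listed gene. Leaving out 1 animal moved the count at 6 h to 5 or 3 (exposed 205 or 209) or to 0 (exposed 206 or 207, air 49, 52 or 53), at 24 h to 1 or 3 (air 54 or 57), at 8 days to 1 or 2 (exposed 223, air 68) and at 19 days to 1 (exposed 233).

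At 0.7 ppm Myoz1, a sarcomere gene, and 1 probe set of Tpm2, a muscle tropomyosin, were lower at 5 days, and nothing else was called at any time. Both belong to muscle, whose transcripts were high in air animals 60 and 61, and neither was called without these animals. Hmox1 stood at most 0.44 ± 0.23 above air at 0.7 ppm (log2, SE, n = 4 per group, at 5 days). Genes of the unfolded protein and integrated stress response lay below air at 24 h (median −0.18 over 19 genes, 7 falls adjusted over the list alone, 0 over all probe sets in limma and 8 at an unadjusted p under 0.05; adjusted p = 0.0156 with an estimated correlation), the only call among the 25 lists below 15 ppm that held. The list lay below the same air animals at 2 and 6 ppm too (medians −0.15 and −0.13; adjusted p = 0.168 and 0.14 with an estimated correlation), and these air animals had a list mean of 9.57 ± 0.05 (log2, SD, n = 4), above the 9.16 to 9.49 of the other air groups. The counts at 6 h, 24 h, 5 days, 8 days and 19 days were 0, 0, 2, 0 and 0 in limma, with 409, 1889, 762, 1021 and 818 probe sets at an unadjusted p under 0.05. At 24 h the count was 48 without exposed animal 134 and 8 or 49 without air animal 54 or 57. At 5 days it was 0 without any of animals 137, 138, 139, 140, 60 or 61 and 25 without air animal 63, and at 8 days it was 1 without exposed animal 143 or air animal 65.

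Air animals were compared across the 5 times to measure what changed without formaldehyde. Clock genes were among those with the smallest p: Dbp, an output of the clock, differed between 24 h and 6 h by −2.15 ± 0.16 (log2, SE, n = 4 per group; adjusted p = 3.44e-22), Bmal1 was higher by 1.91 ± 0.14 and Nfil3 by 1.68 ± 0.18, and the repressors Nr1d1 and Nr1d2 changed by −1.47 and −1.18. Bmal1 stood at 6.68 ± 0.26 at 6 h, 8.60 ± 0.15 at 24 h and 6.72 ± 0.22 at 19 days (SD, n = 4). The water channel gene Aqp1 and the glial sodium channel gene Scn7a were higher at 24 h than at 6 h (1.11 and 1.50) and lower at 8 days (−1.03 and −1.27). In all 3534 probe sets of 1819 genes differed between times, so each exposed group was compared only with air animals of its own time.

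The air animals collected at 6 h in the separate array sets differed as well, which bears on every comparison across sets. Immediate early genes, which respond to stimuli within minutes, were lower in the later set: Egr2 differed by −2.46 ± 0.31 (log2, SE, n = 4 per group; adjusted p = 4.74e-08), Atf3 by −2.43, Gadd45g by −1.75 and Fos by −1.13. Hspa1a differed by −1.27 and Bmpr2, a growth factor receptor, by 1.32. Of the immediate early list, 10 of 25 genes were lower (median −0.59; adjusted p = 3.01e-15 by camera and 0.16 with an estimated correlation), and of stromal and vessel genes 5 of 16 (median −0.56; 0.325). In all 1460 probe sets differed, 774 up and 686 down in the later set. The share of rises, 53.0%, became 63.2% with array medians aligned and 42.4% after cyclic loess. Without air animal 323 or 325 of the later set the count was 883 or 969, and without 50 or 52 of the first set it was 891 or 965.

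**Figure D4:**
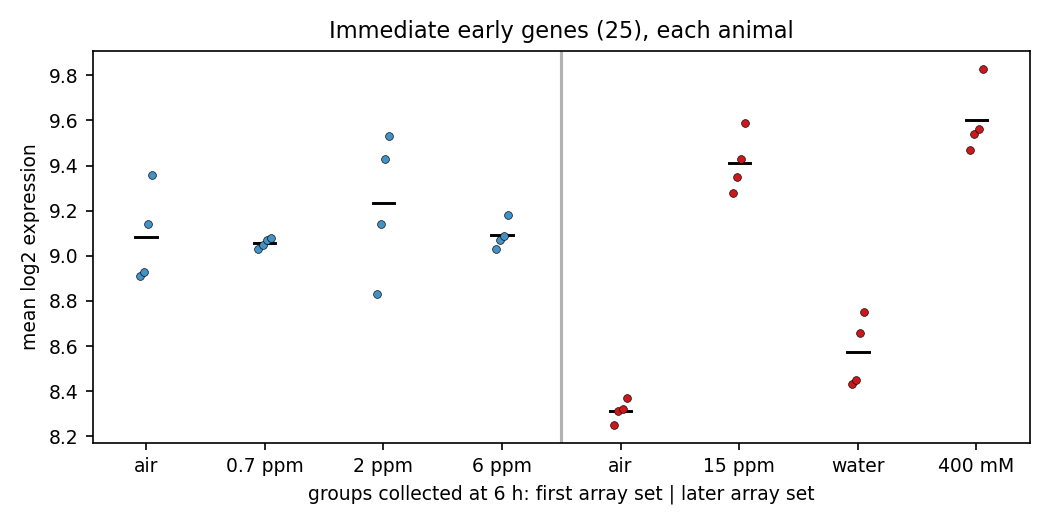
Mean log2 level of the 25 immediate early genes in each animal of the groups collected at 6 h; points are animals, bars are group means and the array sets are shown side by side. The air animals of the first set had a mean of 9.09 and those of the later set 8.31.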

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

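The tests of explanations in this part were chosen only after the results they address were seen, while the tests of differences between effects were set before the data were examined. The effects of instillation and of 15 ppm differed at 273 probe sets, Il6, Ccl7 and Csf3 among their genes. Refits with the residuals of an additive model shuffled among those animals gave up to 1027, and 6 of 100 gave as many, so chance could not be excluded for the count. The effects of 15 and 6 ppm at 6 h differed at 370 probe sets, led by Egr2, Fosl1 and Tnfrsf12a, with at most 43 in other such refits (1 of 100 as large, the real one included). This argues against chance for that count taken alone, as the share was not adjusted over the 22 counts. Per2 was the gene among 4 probe sets whose 6 ppm effect differed between times, with at most 3 in other such refits (1 of 100 as large); with 2 called among the brighter probe sets and shares not adjusted over the 22 counts, chance is not firmly excluded.

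Single animals stood apart from their groups in 17 of 398 group values tested (4.3%), and chance gives about 1 in 20. These values are on the log2 scale. Hmox1 was high in air animal 73 at 19 days (8.41, the others 7.75 to 7.82) and low in animal 223 of 2 ppm at 8 days (8.10, the others 8.84 to 8.96). At 15 ppm Aldh2 was low in animal 341 (11.67, the others 12.17 to 12.18) and Hspb1 high in animal 342 (11.61, the others 10.98 to 11.06). At 6 ppm and 6 h animal 283 was high for Evi2a (6.64, the others 5.57 to 5.67) and Dtx4 (8.48, the others 7.99 to 8.05), and animal 284 was low for the clock list mean (8.17, the others 8.28 to 8.30). Bmal1 was low in animal 219 of 2 ppm at 5 days (5.68, the others 6.20 to 6.39), and Per2 was high in air animal 53 at 6 h (8.75, the others 8.34 to 8.35). At 6 ppm and 5 days Slc3a2 was low in animal 294 (11.29, the others 11.38 to 11.39) and the cholesterol list mean low in animal 293 (8.93, the others 9.03 to 9.04). The squamous list mean was far lower in air animal 65 at 8 days (8.76, the others 10.03 to 10.27), and the cell cycle list mean was high in animal 298 of 6 ppm at 8 days (6.99, the others 6.89 to 6.90). Among the rest were Clec4a in air animal 77 at 19 days (5.63, the others 6.05 to 6.12), Pou2af3 in air animal 321 of the later array set (9.24, the others 9.40 to 9.43), the interferon list mean in instilled animal 369 (9.23, the others 9.78 to 9.85) and the unfolded protein list mean in animal 132 of 0.7 ppm at 24 h (9.49, the others 9.36 to 9.37).

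Clock transcripts differed between exposed and air animals of the same time, with Bmal1 lower at 6 ppm at 6 h, 5 days and 19 days and Per2 higher at 6 h and 5 days; at 5 days Per2 stood at 9.22 ± 0.08 at 6 ppm and 9.16 ± 0.27 at 2 ppm, against 8.31 ± 0.25 in air (SD, n = 4, 5 and 4), and 13 probe sets, Tpm2 of muscle among them, were called in both doses (at most 0 in 100 simulations with common air animals, but 0 to 1 in 6 splits that gave each dose its own air animals). Of 7 clock calls at 2 and 6 ppm, 6 held after cyclic loess. It was run on values already normalized, so it cannot decide whether the authors' normalization plays a part. Exposed animals collected later in the day than air animals could give differences of this kind: at 24 h, where air animals held another clock phase, the 6 ppm animals lay 27.2% further towards the phase of the other times (10.8 ± 12.7 against −16.4 ± 14.5, SD, n = 4 each, exact permutation p = 0.0571, the smallest possible 0.0286). At 2 and 0.7 ppm the shifts were 23.3% and 12.7% (exact permutation p = 0.0571 and 0.143). An effect on Per2 at 6 h that grows with dose is open too: the 15 ppm effect at 6 h lay −0.92 from that of 6 ppm with each dose against its own air animals (adjusted p = 0.00211), but −0.27 (0.203) when both were set against the first set's air animals. In the first set at 6 h the Per2 mean was 8.44 in air and 8.80, 9.05 and 9.05 at 0.7, 2 and 6 ppm. At 8 days the Per2 mean fell with dose, from 9.18 at 0.7 ppm to 9.05 at 2 ppm and 8.87 at 6 ppm (air 8.61). At 5 days it rose with dose (8.62, 9.16 and 9.22 at 0.7, 2 and 6 ppm). Collection time and dose cannot be told apart here, since the time of day of each group is unknown and 4 animals per group left the shift undecided.

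Immediate early transcripts were lower in the later set's air animals than in the first set's (median −0.59 over 25 genes), which changes what 15 ppm appears to do: 13 genes rose against the later set's air, and 7 rose and 2 fell against the first set's, with Fosb up by 2.08 and 0.01, and Fosl1 by 3.41 and 2.99. The later set's air animals had the lowest mean RNA integrity number of the 24 groups (7.475 ± 0.222, SD, n = 4). It was 8.15 ± 0.238 in the first set's air and 7.95 ± 0.238 at 15 ppm. A linear effect of RNA integrity is argued against. Within groups the list mean changed by −0.01 per unit of RNA integrity number (95% interval −0.214 to 0.201, 85 arrays), where a slope of 1.143 would be needed. A slope within groups cannot decide on differences in RNA quality that go with the array set. Olfactory tissue is argued against as well: the median was −0.62 with the olfactory list mean as a covariate. After cyclic loess it was −0.62 too. Cyclic loess was run on values already normalized and cannot undo the authors' processing, so the authors' normalization stays open. The handling of the animals and the days of collection differ with the array set and cannot be separated from it, and no biological explanation was tested.

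Skeletal muscle transcripts were high in air animals 60 and 61 at 5 days, with list means of 7.49 and 7.59 against 6.27 and 5.11 in animals 62 and 63, Acta1 at 11.19 and 11.09 and Ckm at 10.07 and 10.00 (log2). Muscle tissue in these samples is a candidate explanation: 13 of 19 further muscle genes were higher in both animals than in each of 23 other air animals, with a median excess of 1.23. Animals 60 and 61 were picked as those with the highest mean of the whole list, which held these genes. That count is therefore not an independent test. Of the 24 genes of the list 1, Des, is also on another list. A fall of muscle transcripts under formaldehyde at 5 days is argued against. Of 13 exposed animals at 5 days, 12 lay within the range of the 21 air animals of other times (5.04 to 6.68). At other times a fall stays open. At 0.7 ppm the list median was −0.44 at 6 h and −0.53 at 8 days (adjusted p = 0.0328 and 0.0654 by camera with an estimated correlation). At 2 ppm and 8 days it was −0.35 (0.166). It was 0.42 and 0.21 at 24 h at 2 and 0.7 ppm, and between −0.21 and 0.07 at 6 ppm at these other times. Without animals 60 and 61 the muscle list median at 5 days went from −0.93 to −0.12 at 6 ppm, from −0.88 to −0.09 at 2 ppm and from −0.93 to −0.27 at 0.7 ppm. Part of that shrinkage follows from how these animals were picked. The lists with all animals held with an estimated correlation (adjusted p = 0.00738, 0.0092 and 9.31e-06), with 20, 19 and 20 falls adjusted over the list alone.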

How the results depend on the processing

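The olfactory covariate, the first set's air animals as controls and the omission of air animals 60 and 61 were tests chosen only after the results were seen. Among the exposures, those to 15 ppm and by instillation depended least on single animals: their 24 genes with the largest changes were called whichever animal was left out, and the counts ran from 1781 to 2549 and from 5138 to 7061. Hmox1 and Srxn1, the genes called most often at 6 ppm, were called in every fit that left out 1 animal at 8 and 19 days, and Srxn1 at 5 days. The balance of rises and falls turned after cyclic loess at 6 ppm, from 46.1% up to 69.3% up at 6 h and from 28 up and 100 down to 61 and 38 at 19 days, and in the air sets, where the share of rises went from 53.0% to 42.4%. Against the first set's air animals at 15 ppm, Hspa1a went from 0.83 to −0.44 and the clock list median from −0.29 to 0.03.

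With each animal left out in turn, the counts at 6 ppm ran from 15 to 197 at 6 h (lowest without air animal 49, highest without exposed 283), 0 to 20 at 24 h, 19 to 60 at 5 days, 4 to 15 at 8 days and 28 to 128 at 19 days. At 2 ppm they ran from 0 to 5 at 6 h, 0 to 3 at 24 h, 2 to 122 at 5 days, 0 to 2 at 8 days and 0 to 1 at 19 days. At 0.7 ppm they were 0 in each such limma fit at 6 h and 19 days and ran from 0 to 49 at 24 h, 0 to 25 at 5 days and 0 to 1 at 8 days. The air times gave 2875 to 3546, the air sets 883 to 1125, the 6 ppm effect between times 3 to 8, 15 ppm against instillation 104 to 574 and 15 against 6 ppm 214 to 464. In all 71 of these fits moved a count by more than 1.5 times and 171 did not.

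With an intensity trend and a robust prior all 22 counts stayed within 1.5 times. Centring arrays moved the 6 ppm counts at 24 h to 2 and at 19 days to 69, and cyclic loess moved those of 6 ppm at 24 h to 0 and of 2 ppm at 6 h to 7; the other 20 counts stayed with each, and the cause was not tested. With only the brighter probe sets, the counts were 0 and 227 for 6 ppm at 24 h and 19 days, 12 and 1 for 2 ppm at 5 and 8 days, 0 for 0.7 ppm at 5 days and 2 for the 6 ppm effect between times; fewer probe sets were tested. With only the compared groups in the fit, which leaves fewer arrays to estimate the spread, 6 ppm gave 7, 0, 3, 0 and 1 at the 5 times, 2 ppm gave 0 at 6 h and at 5 days, and 0.7 ppm gave 4 at 24 h and 0 at 5 days. That fit gave 3649 for instillation, 2910 for the air sets and 84 for 15 ppm against instillation. Of the genes changed 1.5-fold in simulated data for 6 ppm at 6 h it found 48.2%, against 77% with all arrays. For these zeros the limma counts at an unadjusted p under 0.05, with all arrays, are given with each comparison.

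With the olfactory covariate the counts at 6 ppm were 139, 9, 63 and 347 at 6 h, 24 h, 5 days and 19 days, at 2 ppm 2, 1 and 1 at 6 h, 24 h and 8 days, and at 0.7 ppm 1 at 8 days; the 6 ppm effect between times gave 20 and 15 ppm against instillation 486. The cause was not tested. At 15 ppm the count was 4184 against the air animals of both sets and 4763 against those of the first set, with 937 rises and 678 falls shared. Without air animals 60 and 61 the counts at 5 days were 12, 0 and 0 at 6, 2 and 0.7 ppm, against 55, 41 and 34 without animals 62 and 63, so the loss is tied to which animals were left out and not to their number.

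Of 74 list calls for 6 and 15 ppm and instillation, 12 held with an estimated correlation, 29 with fry, 60 with the brighter probe sets, 70 with centred arrays and 41 whichever animal was left out. The rest lost the call, and their directions were not counted. Pseudocount alternatives were not run, as the values were already logarithms. Signal over background limits dim probe sets, and arrays give no counts from which to set a floor.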

Other observations

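The tests in this part were chosen only after the data were seen, apart from the refits of other splits of the animals. Ribosome assembly genes rose with strong exposure: of 21 ribosome biogenesis genes 18 rose at 15 ppm (20 adjusted over the list alone; median 0.58; adjusted p = 4.08e-05 with an estimated correlation), among them Nop56, a core factor of ribosomal RNA modification, by 1.14 and the nucleolar gene Gnl3 by 1.52 (log2). After instillation 17 rose (17 adjusted over the list alone; median 0.42; 0.0106), with Nop56 up by 1.19 and Gnl3 by 1.46. At 6 ppm the list median was 0.16 at 8 days (4 rises adjusted over the list alone, adjusted p = 0.0461 with an estimated correlation) and 0.16 at 19 days (1 rise, 7 adjusted over the list alone, 0.0548). It was 0.12, 0.02 and 0.13 at 6 h, 24 h and 5 days, where the list did not hold with an estimated correlation (adjusted p = 0.0812, 0.861 and 0.066). At 2 ppm and 8 days it was 0.16 too, against the same air animals as 6 ppm (adjusted p = 0.0953 with an estimated correlation). The shift at 8 days was thus not particular to 6 ppm, and a deviation of these air animals stays possible. In the other comparisons at 0.7 and 2 ppm the median lay between −0.08 and 0.05. None of these 21 genes belongs to the other lists.

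Some markers of rare epithelial cells, chosen after their values were seen, were lower. Pou2af3, of tuft cells, fell by 1.13 at 15 ppm, by 1.02 after instillation, and by 0.73 and 0.68 at 6 ppm at 6 h and 19 days. Ascl3, of ionocytes and duct cells, fell by 0.96 at 6 ppm at 19 days and by 0.94 after instillation, and Foxi1 fell by 0.72 at 6 ppm at 19 days; at 15 ppm neither was called (−0.35 and 0.05). At 6 ppm, Foxi1 at 19 days lost its call in 4 of 8 fits that left out 1 animal, and Pou2af3 at 6 h in 3 of 8. No list of such cells was tested. Glucocorticoid-responsive genes lay above air in some groups and below it at 24 h: the median over 13 genes was 0.34 at 2 ppm and 6 h (6 rises adjusted over the list alone; adjusted p = 0.001 with an estimated correlation), 0.30 at 2 ppm and 5 days (5; 0.0092), 0.38 at 0.7 ppm and 6 h (4; 0.0019) and 0.35 at 0.7 ppm and 8 days (6; 0.000308). Tsc22d3, a glucocorticoid target, stood 0.61 and 0.62 above air at 0.7 ppm at these times and was not called. At 6 ppm the median was 0.44 at 6 h (5 rises adjusted over the list alone, adjusted p = 0.0812 with an estimated correlation) and 0.34 at 5 days (3, 0.066), and at 0.7 ppm and 5 days it was −0.04 (0.761). At 6 ppm it was 0.02 at 8 days (0.734) and 0.19 at 19 days (0.11). At 24 h the medians were −0.25, −0.19 and −0.34 at 6, 2 and 0.7 ppm (1, 1 and 2 falls adjusted over the list alone), and these did not hold with an estimated correlation (adjusted p = 0.144, 0.176 and 0.0818). Of the 13 genes, 4 are also on other lists: Per1, Sgk1, Dusp1 and Ddit4. These list tests were adjusted among 3 lists per comparison only. All doses of a time were set against the same air animals, so their agreement at 6 h and at 24 h is not independent. A deviation of those air animals could give it.

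Transcripts that rose at 15 ppm may also be raised at 6 ppm as a set, a hypothesis formed on these data. The mean of 82 genes that rose at least 2-fold at 15 ppm, without immediate early genes, was higher at 6 ppm than in air by 0.20 (95% interval 0.07 to 0.32; above 0 at 5 of 5 times; permutation p within times = 0.00243, adjusted over 2 tests 0.00486; 41 animals). Genes called at 6 ppm by themselves are among the 82 genes, including Hmox1, Srxn1, Tnfrsf12a, Areg, Slc7a11 and Osgin1. The set was not tested without them, so how far they carry the mean is open. At single times the differences were 0.15, 0.09, 0.11, 0.31 and 0.32, with exact permutation p of 0.143, 0.4, 0.457, 0.119 and 0.0857. At 0.7 and 2 ppm together the mean difference was −0.01 (95% interval −0.12 to 0.10; above 0 in 4 of 10 comparisons; permutation p = 0.809; 62 animals), an interval that leaves a rise of up to 0.10 open.

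The first axis of the differences between animals within groups held 26.9% of that variance and followed the mean of the olfactory list over 98 animals (Pearson's r = 0.957 and Spearman's rho = 0.972, each with a permutation p of 1e-04, the smallest these permutations can give; r = 0.954 without the 2 animals farthest from the median). The olfactory lining was to be discarded at dissection per the labels.

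Other splits of the animals were refitted for the counts below, the real split included in the number. No other split gave as many calls for 6 ppm at 6 h (76 called, at most 2 in the other splits, 1 of 35 as large), 5 days (37, at most 5, 1 of 35) and 19 days (128, at most 1, 1 of 35). At 5 days 12 were called without air animals 60 and 61. The real split was the largest also for 15 ppm (2636, at most 310, 1 of 35), instillation (6892, at most 3207, 1 of 35), the air times (3534, at most 396, 1 of 100) and the air sets (1460, at most 11, 1 of 35). These shares argue against chance for each count taken alone. A share of 1 of 35 is the smallest that 35 splits can give, and none was adjusted over the 22 counts. For 6 ppm at 8 days (9, at most 11, 2 of 100) and 2 ppm at 5 days (23, at most 257, 4 of 100) few splits gave as many calls, but another split gave more than the real one, and the shares were not adjusted over the 22 counts, so chance is not firmly excluded. Chance could not be excluded for 6 ppm at 24 h (1 called, at most 8, 16 of 35 as large), 2 ppm at 6 h (1, at most 2, 7 of 35) and 0.7 ppm at 5 days (2, at most 14, 4 of 35). Where the real count was 0, each split gives as many and the refits decide nothing: these were 2 ppm at 24 h (0, at most 32, 35 of 35), 8 days (0, at most 50, 100 of 100) and 19 days (0, at most 1, 35 of 35), and 0.7 ppm at 6 h (0, at most 0, 35 of 35), 24 h (0, at most 13, 35 of 35), 8 days (0, at most 4154, 100 of 100) and 19 days (0, at most 8, 35 of 35). The limma counts at an unadjusted p under 0.05 for the zeros were 1751, 1317 and 2682 at 2 ppm and 409, 1889, 1021 and 818 at 0.7 ppm. The splits with 4154, 257, 50 and 32 calls point to a structure of the animals; in the split with 4154 calls at 8 days the groups differed by 1.38 in the mean of the olfactory list.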
